A study of Mus musculus with 12 samples.

How the data were processed

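RNA-seq was done on mouse ESC and differentiating cultures of 3 lines, in 12 libraries. Per the labels the libraries were poly-A selected and strand-specific by the dUTP method. The authors' processing notes name the mouse genome build mm9, Bowtie and DESeq without versions, roles or parameters; the counter, its strand setting and the annotation release are not given. The deposited files hold raw counts per Ensembl gene, whole numbers with no normalization. The authors also deposited RPKM values (reads scaled by gene length and library total), whose denominators are not stated; within a gene they were checked to be proportional to the counts (largest relative spread 0.0018% over 7943 genes) and were used for no comparison. The files list 37583 genes, and 25 gene names turned into dates by a spreadsheet were restored from their identifiers. A GRCm38 annotation gave GC content (32860 genes) and transcript length only; coordinates are those of the files.

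The labels give the line, the day and a replicate number (b1 or b2) but not what a replicate is, so replicates may not be separate cultures. Day 0 is not unambiguous: the protocol forms embryoid bodies on Day 0 and adds retinoic acid (1 uM) and SAG (0.5 uM) on Day 2, while the source names count Day 4 from that addition. Whether d56d79 was made from d56 is not given. Whether several clones were used is not given either, so 1 line per genotype is assumed throughout. Since the deletions remove CTCF sites and no gene, no transcript checks a library's genotype label.

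Counts were analysed in R 4.3.3 with edgeR 4.0.16: TMM scaling (factors 0.80 to 1.13), filterByExpr at its defaults over the 8 groups (18436 genes kept), and the robust quasi-likelihood test with 1 coefficient per group over all 12 libraries (4 residual degrees of freedom, biological coefficient of variation 0.61). Groups with 1 library are assumed to vary like the others. Genes were called at a Benjamini-Hochberg adjusted p under 0.05, two-sided, in each of 9 comparisons. The scaling, filter, test, comparisons, gene lists and rule for named genes were set before the data were examined. Overlaps between days used Fisher's exact test, two-sided. ESC libraries of d56 and WT were compared by ratios of CPM with exact 95% binomial intervals, and lists by their rank among 10000 random lists of like expression in 20 bins (pseudocount 0.5 CPM).

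Total counts ran from 5617322 to 17554089 per library. A count of 0 in a library allows up to 3 counts, which is 0.171 to 0.534 CPM of the library totals without the TMM factor. Log2 ratios within a replicate are of CPM for Hoxa genes and of CPM plus 0.5 for other genes. A fold against a group without reads is given as at least its value with 3 counts over that whole group. It takes the other group's counts as exact, so with few counts there the true fold can be smaller. Intervals cover counting error only, and bounds only that of the group without reads, and reads are not independent molecules. Hoxa3's gene model spans Hoxa4 to Hoxa6, and antisense transcripts overlap several Hoxa genes, so reads of overlapping genes may be assigned to either or to neither.

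Gene lists (38, of which 37 had at least 5 tested members; no mitochondrially encoded gene is in the files) covered the Hox clusters, cell types, pathways and other cell types the cultures could hold. They were tested with camera in limma 3.58.1 on log2 CPM with a prior count of 2 and a preset correlation of 0.01, and again with a correlation estimated per list. In each list, genes were also adjusted over the list alone. Members named are the 2 to 4 with the smallest p in the fit they are quoted from.

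Named genes are, by the rule set beforehand, the 11 Hoxa genes and the genes next to the cluster; in each comparison, up to 10 rises and 10 falls with the largest fold change among called genes with at least 5 CPM in the higher group and no overlap between the groups' libraries, of which a part with known functions is given, picked after the values were seen; the list members above; and the 5 largest and 5 smallest ESC ratios. The same rule was applied to the batch-adjusted fit, with no overlap asked within each batch. The genes named in the overlap of days and the list members named in the ESC comparison, which has no test, were chosen after their values were seen.

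Pairing and batch were checked across genes: the replicate 2 minus replicate 1 differences of the 4 groups with 2 libraries correlated with each other at 0.80 to 0.95. A replicate block was planned as an alternative; it called 0 genes for d56 against WT at Day 4 and at Day 0. As the d56d79 libraries cluster with replicate 2 and the replicate difference varied with day, these alternatives were added after seeing the data: the block with d56d79 placed with replicate 2 (also 0 and 0), a block with an effect for each day (batch-adjusted fit; 2 residual degrees of freedom, biological coefficient of variation 0.15, prior degrees of freedom 488.57; 119 and 186 genes), and the latter with each library's trend on GC content and transcript length removed by splines with 5 degrees of freedom (41 and 46 genes; median total degrees of freedom 12.9, against 491 without the correction). The same correction was applied to the ESC ratios, also after seeing the data. Principal components were computed on all tested genes and on the 2000 most variable; the choice between these sets was changed after a first result was seen, so both are given. ESC libraries lay on the replicate 1 side. Each of the 66 pairs of libraries differed beyond counting noise (chi-square over degrees of freedom 8.32 to 431; 119 to 300 between replicates), so no library is a copy of another.

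The alternatives set beforehand were DESeq2 size factors and library totals in place of TMM, no filter or at least 1 CPM in at least 2 libraries, the DESeq2 1.42.0 Wald test, a fit of only the groups compared, the replicate block, an estimated list correlation and leaving out each replicate. Alternatives for normalized values did not apply, since counts were deposited. The pseudocount of 0.5 CPM and the prior count of 2 were not varied. The scaling moved the median log2 fold change of all genes by over 0.1 for WT Day 4 against Day 0 (-0.19 with TMM, -0.13 with DESeq2 size factors, 0 with totals); no called gene value changed sign under another scaling.

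The pipeline was tested on simulated data with 100 genes changed by each fold. With the spread of the libraries, the group fit recovered 1 gene of 100 at 4-fold and 50 at 16-fold for d56 against WT at Day 4, and 0 and 14 for d56d79. With batch effects simulated, the batch-adjusted fit recovered 100 and 100 with 7 false calls, and 97 and 100 for d56d79 with 10 false calls. With GC and length trends simulated as well, the corrected fit recovered 100 and 100 with 6 false calls for d56. These simulations gave every gene the batch-adjusted fit's own coefficient of variation, 0.15, and batch effects of the form that fit removes. They therefore cannot show whether that spread holds for the genes of these libraries. Tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.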

Results

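Poly-A RNA was sequenced from mouse embryonic stem cells (ESC) and from cultures differentiated from them towards motor neurons with retinoic acid and SAG, an activator of Hedgehog signalling. The cells came from 3 lines: wild type (WT), a line lacking a CTCF site between Hoxa5 and Hoxa6 (d56), and a line lacking that site and a second between Hoxa7 and Hoxa9 (d56d79). CTCF is a DNA-binding protein of chromatin boundaries, and the series asks whether it insulates parts of the HoxA cluster during neurogenesis. The 12 libraries fall into 8 groups. WT and d56 at Day 0 and at Day 4 had 2 libraries each. ESC of WT and of d56, and d56d79 at Day 0 and at Day 4, had 1 library each. Total counts were 10505006 (WT) and 8818429 (d56) in ESC. At Day 0 they were 10687681 and 10147711 in WT, 8233015 and 10229450 in d56, and 5617322 in d56d79. At Day 4 they were 9517324 and 9891132 in WT, 9216160 and 14336432 in d56, and 17554089 in d56d79. Values are CPM (counts scaled to each library's total times its TMM factor), given as mean ± SD.

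Apart from day, the libraries differed most by replicate number. Over all 18436 tested genes the first principal component (58.3% of the variance) followed day and the second (25.8%) the replicate. Over the 2000 most variable genes these shares were 79% and 11.2%. Both d56d79 libraries, numbered replicate 1, lay with the replicate 2 libraries. At Day 4 the d56d79 library had r = 0.970 and 0.972 across genes with the replicate 2 libraries of WT and d56, against 0.802 and 0.785 with their replicate 1 libraries. The replicate difference followed GC content: the median log2 ratio of replicate 2 to replicate 1 was 1.35 in the fifth of genes with the lowest GC and -1.38 in the fifth with the highest. Each comparison is therefore given from the fit on groups planned beforehand (group fit), and from a fit with a batch effect for each day (batch-adjusted fit), chosen after seeing the data, in which the d56d79 libraries stand with replicate 2. The batch-adjusted fit has 2 residual degrees of freedom, so its p-values rest on a spread pooled over genes (median total degrees of freedom 491). With a correction for GC content and length added, that median was 12.9, so a call can be lost there while its fold stays alike.

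**Figure D1:**
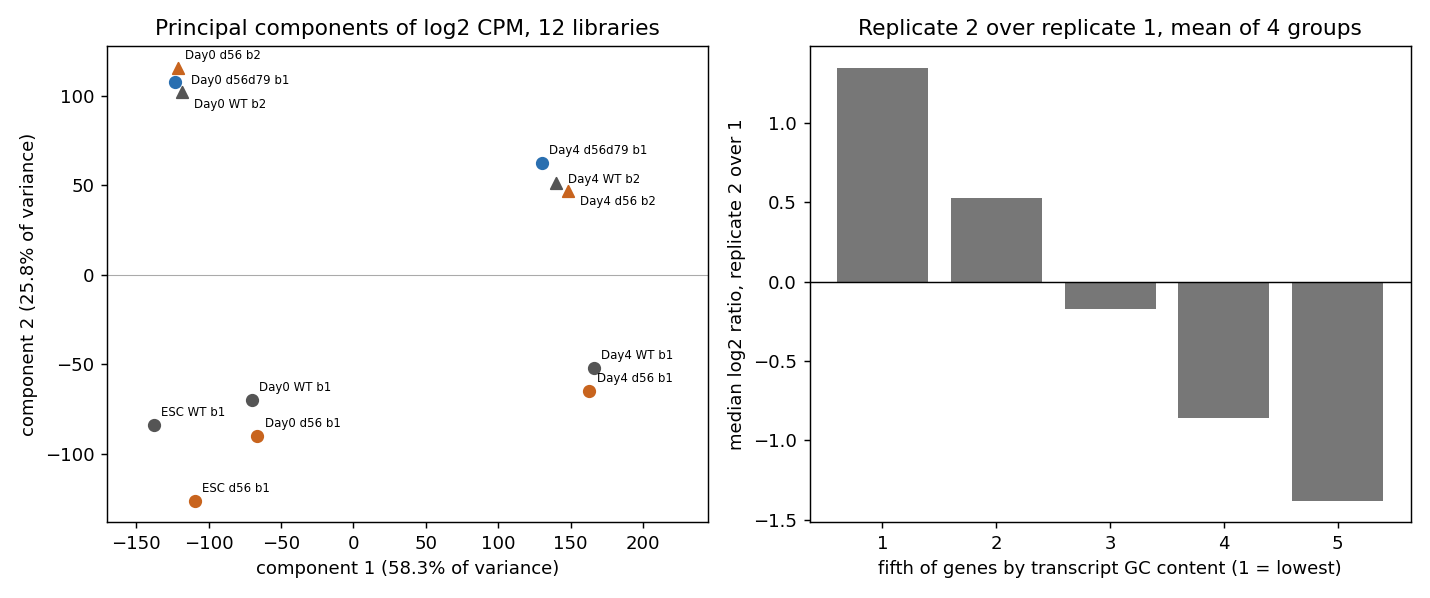
Left, the 12 libraries on the first 2 principal components of log2 CPM, with shape for replicate and colour for line; the replicate 2 libraries and both d56d79 libraries lie apart from the rest on the second component (25.8% of the variance). Right, bars of the median log2 ratio of replicate 2 to replicate 1 (Day 0 and Day 4 groups) in 5 equal groups of genes by GC content, falling from 1.35 to -1.38.

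Between Day 0 and Day 4 the WT cultures lost pluripotency transcripts and gained neuronal and Hox transcripts. Utf1, a stem cell chromatin factor, stood at 359 ± 90.4 CPM at Day 0 and had no read at Day 4, and the pluripotency factor Nanog went from 47.7 ± 30.8 CPM to no read (n = 2 each). Of 20 naive pluripotency genes 8 fell and none rose, and of 11 epiblast genes 5 fell and none rose, among them Zic3 (log2 fold change -9.34, SE 1.04) and the DNA methyltransferase Dnmt3b (-6.74, SE 0.82). Of 20 pan-neuronal genes 14 rose and none fell, among them Dcx (8.09, SE 0.85) and Gap43 (5.83, SE 0.64). Of 15 genes of postmitotic motor neurons 9 rose and none fell, led by the homeodomain factors Mnx1 (7.70, SE 0.74), Isl1 (8.0, SE 0.85) and Lhx4 (7.82, SE 0.89).

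Hox genes rose with them. In the HoxA cluster Hoxa4 (log2 fold change 5.39), Hoxa5 (6.09) and Hoxa6 (5.86) rose, with adjusted p = 0.0377, 0.0196 and 0.0275, and the same 3 genes passed adjusted over the list alone. Of 10 HoxB genes 6 rose, among them Hoxb7 (6.78, SE 0.66) and Hoxb4 (6.52, SE 0.75). Hoxc5 went from 0.044 ± 0.0622 to 110 ± 46.5 CPM, and Shh, the floor plate signal, from 0.0582 ± 0.0823 to 63.5 ± 67.1 CPM. The glutamate receptor gene Gria2 reached 74.1 ± 33.3 CPM from no read at Day 0. The group fit called 811 of 18436 genes, 483 higher and 328 lower at Day 4, and the batch-adjusted fit 11557, of which 810 were called in the same direction in both. The call rests on every library: without any 1 of the 4 WT libraries the count was 0, by edgeR, with 2431 to 3780 genes at an unadjusted p under 0.05, and DESeq2 on all libraries called 3079. The list tests by camera with a preset correlation (adjusted p = 4.95e-08 naive pluripotency, 2.7e-07 epiblast, 2.7e-17 pan-neuronal, 6.24e-12 motor neuron, 3.11e-06 HoxB, 0.00179 HoxA) were lost with an estimated correlation (adjusted p = 0.102 for the first 4, 0.172 and 0.302).

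The comparison of d56 with WT at Day 4 asks what follows the loss of the site between Hoxa5 and Hoxa6. Hoxa7 (ENSMUSG00000038236; mm9 chromosome 6, 52164490 to 52171853), the next gene but one beyond that interval, stood at 81.5 ± 12.1 CPM in d56 and 3.21 ± 0.638 CPM in WT (n = 2 each). The libraries were at 90.1 and 72.95 CPM in d56 and at 2.76 and 3.66 CPM in WT, a log2 ratio of 5.03 within replicate 1 and 4.32 within replicate 2. Hoxa7 rose by a log2 fold change of 4.65 (SE 0.29, adjusted p = 1.25e-41) in the batch-adjusted fit, which ranked it first of all genes. In the group fit by edgeR the value was 4.66 (SE 0.92), past the threshold adjusted over the list alone (adjusted p = 0.0129) and not over all genes (adjusted p = 1). That list-alone call was lost in 3 of 14 alternatives, which left out WT replicate 1, WT replicate 2 or d56 replicate 1 at Day 4 (range 6.77e-45 to 0.168 over the 14). At Day 4 no gene of the HoxB, HoxC and HoxD lists or of the HoxA neighbours was called in either fit. The paralogue Hoxb7 differed by 0.07 (SE 0.23) in the batch-adjusted fit.

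Around Hoxa7 the cluster differed less. Hoxa6, between the deleted site and Hoxa7, was at 26.5 ± 3.27 CPM in d56 and 18.29 ± 16.26 CPM in WT, with log2 ratios of -0.05 within replicate 1 and 1.83 within replicate 2. It passed in the batch-adjusted edgeR fit adjusted over the list alone (0.84, SE 0.30, adjusted p = 0.0192) and not over all genes (adjusted p = 0.314). That list-alone call was lost with GC and length correction (0.60, SE 0.46), and 1 of 14 alternatives to the group fit passed. Hoxa9 (ENSMUSG00000038227) was at 2.15 CPM in d56 and 0.4 CPM in WT and passed in the batch-adjusted fit (2.36, SE 0.56, adjusted p = 0.00953), a call lost over all genes with GC and length correction (2.35, SE 0.70, adjusted p = 0.465). All 9 WT counts were in replicate 2, and over the alternatives to the group fit the value ran from 1.4 to 7.53, with 2 of 14 past the threshold adjusted over the list alone. Hoxa5 had 532.06 against 630.14 CPM, Hoxa4 104.06 against 112.4, Hoxa3 114.71 against 115.26, Hoxa2 41.55 against 46.27 and Hoxa1 69.1 against 95.55, none called in either fit. Hoxa11 had no read at Day 4. The antisense transcript Hoxaas3, which overlaps the end of Hoxa7, was at 31.74 and 18.24 CPM in d56 and 46.07 and 22.52 CPM in WT. Over the 10 tested Hoxa genes, 1 passed adjusted over the list alone and 0 over all genes by edgeR in the group fit (1 over all genes by DESeq2), and 3 and 2 in the batch-adjusted fit.

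**Figure D2:**
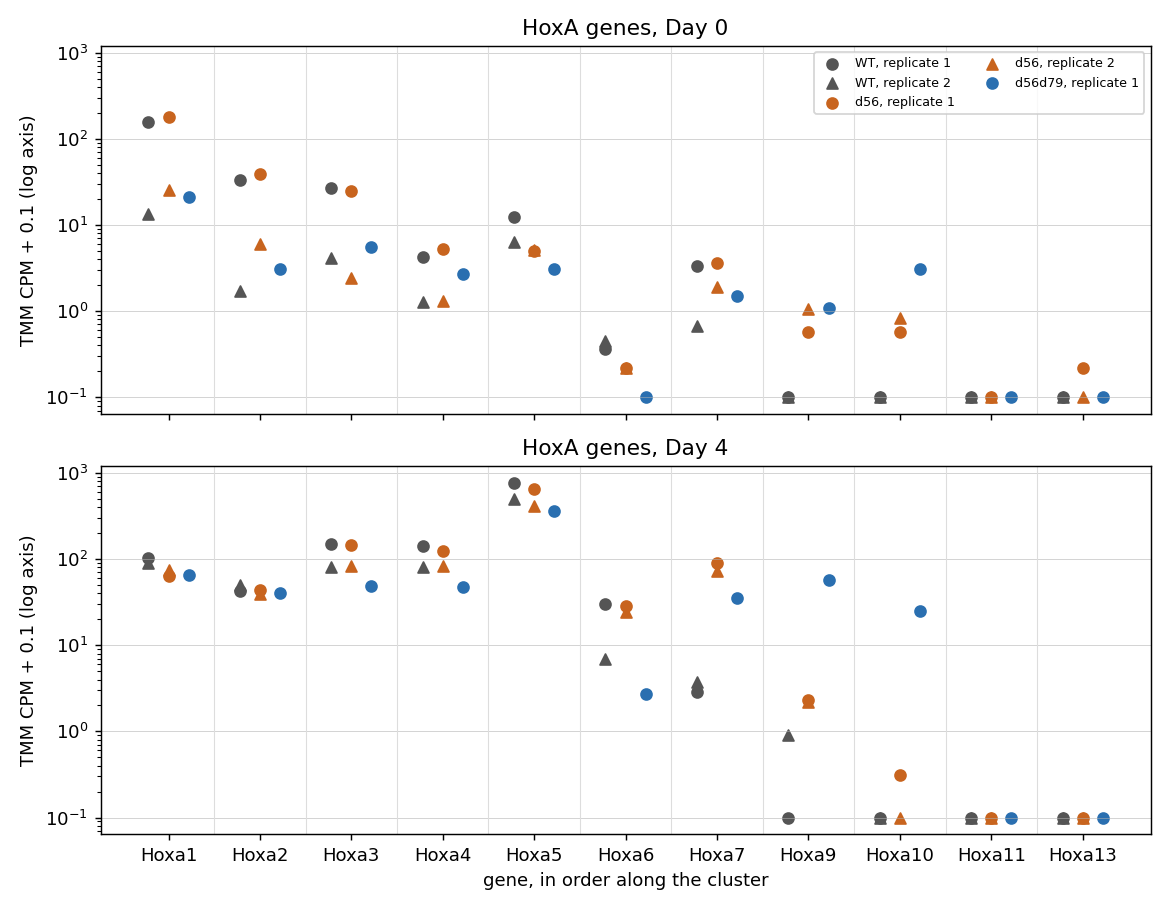
CPM + 0.1 on a log axis of each Hoxa gene, in order along the cluster, in every library at Day 0 (top) and Day 4 (bottom). Circles are replicate 1, triangles replicate 2, grey WT, orange d56 and blue d56d79. At Day 4 Hoxa7 lies at 90.1 and 72.95 CPM in d56 and 35.13 CPM in d56d79 against 2.76 and 3.66 CPM in WT, and Hoxa9 and Hoxa10 reach 57.34 and 25.06 CPM in d56d79.

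Outside the cluster, 4 of 23 tested imprinted genes were called between d56 and WT at Day 4 in the batch-adjusted fit. Grb10, an adaptor of growth factor receptors, was at 17.8 ± 9.38 CPM in d56 and 516 ± 31.6 in WT, and Plagl1, a zinc finger factor, at 1.24 ± 0.421 and 50.2 ± 15.6 CPM. Nnat was at 4490 ± 1650 CPM in d56 and 777 ± 188 in WT, and the noncoding RNA H19 at 1570 ± 1950 and 90.1 ± 87 CPM. In the batch-adjusted fit Grb10 fell by 4.93 (SE 0.27) and Plagl1 fell by 5.33 (SE 0.36) on the log2 scale, while Nnat rose by 2.50 (SE 0.21) and H19 by 3.53 (SE 0.30). With GC and length correction Plagl1 and Nnat kept the call, and Grb10 (-4.82, SE 0.45, adjusted p = 0.0683) and H19 (3.41, SE 0.38, adjusted p = 0.0808) lost it. Within replicates 1 and 2 the log2 ratios were -5.4 and -4.43 for Grb10 and -4.78 and -4.92 for Plagl1. In the group fit Grb10 and Plagl1 passed only adjusted over the imprinted list alone (edgeR adjusted p = 0.00603 and 0.00841). Of single genes outside the lists, the globin genes Hbb-y (3.22, SE 0.48) and Hbb-bh1 (3.17, SE 0.52) were higher in the batch-adjusted fit, at 11.1 ± 7.64 and 6.05 ± 3.4 CPM in d56, and kept the call with GC and length correction (adjusted p = 0.0386 and 0.0268), where Hba-x (3.14 before and 2.83 after, adjusted p = 0.0874), Hbb-b1 (3.09 and 2.85, 0.169), Hba-a2 (2.83 and 2.49, 0.0755) and Hba-a1 (2.50 and 2.18, 0.0599) lost it at folds little changed. Globin genes were no list set beforehand, and their near-identical copies can share reads. In the d56d79 library of Day 4, which lacks the same site, each of these globin genes lay between the WT libraries. Their levels there ran from 0.158 CPM (Hbb-b1) to 1.42 CPM (Hbb-y).

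Floor plate genes were lower in d56 at Day 4. All 8 tested members had negative values in the group fit (median log2 fold change -1.94), and in the batch-adjusted fit 5 fell, among them Arx (-2.67, SE 0.43), Sulf1 (-1.39, SE 0.23), Foxa1 (-2.08, SE 0.36) and Shh (-1.88, SE 0.30). Shh was at 111 and 16.1 CPM in WT and at 16.7 and 8.32 CPM in d56, so its ratio was larger within replicate 1 (-2.7) than within replicate 2 (-0.91). After GC and length correction 2 floor plate genes kept the call, Arx and Sulf1 (adjusted p = 0.0268 each), and Foxa1 (-2.14, adjusted p = 0.107), Shh (-1.96, adjusted p = 0.382) and Foxa2 (-1.56, adjusted p = 0.0977) lost it. The list passed by camera (adjusted p = 6.72e-14, and 3.01e-08 with the batch) and not with an estimated correlation (adjusted p = 0.664 and 0.725). In the hypoxia and glycolysis list 15 of 17 values were positive (median 0.57, adjusted p = 0.000199, lost at 0.664 with an estimated correlation), of which Ldha, lactate dehydrogenase, rose in the batch-adjusted fit (1.36, SE 0.22). The endoderm list (median -1.06, adjusted p = 4.51e-05, and 0.895 with an estimated correlation) had 4 falls, among them Foxa1, Foxa2 and Col4a1, and 1 rise, Sparc, of 16 in the batch-adjusted fit. The epidermis list (adjusted p = 0.00501, and 0.664 estimated) had 1 fall of 7, Cdh1 (-1.83, SE 0.33). The HoxA list itself passed upwards (adjusted p = 0.000199) with a median of 0 and a mean of 0.96, and not with the batch (0.19) or an estimated correlation (0.664). No gene of the postmitotic motor neuron and pan-neuronal lists was called over all genes in either fit. In the lists of motor column genes and of hindbrain and visceral motor neurons 1 gene each fell in the batch-adjusted fit, Gata6 (-2.78, SE 0.76, adjusted p = 0.0447) and Gbx2 (-1.19, SE 0.30, adjusted p = 0.0329). Of the genes named from these other lists, Ldha, Sparc and Cdh1 kept the call after the correction, and Col4a1 (-0.85), Gata6 (-2.83) and Gbx2 (-1.35) lost it.

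By count, edgeR called 0 genes between d56 and WT at Day 4 in the group fit, with 56 at an unadjusted p under 0.05 where chance gives 922. DESeq2 called 3: Grb10, Plagl1 and Hoxa7. The batch-adjusted fit called 119 genes, 62 higher and 57 lower. A single replicate term for both days gave 0 with 260 at an unadjusted p under 0.05, and a correction for GC and length beside the batch gave 41. Each genotype is taken as 1 line, so a difference between lines cannot be told apart from an effect of the deletion.

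At Day 0 the same comparison gave no detectable difference for Hoxa7, at 0.54 (SE 0.40, adjusted p = 0.989) in the batch-adjusted fit and 0.46 (SE 0.83) in the group fit. Its log2 ratio was 0.12 within replicate 1 and 1.65 within replicate 2. Adjusted over the list alone in the batch-adjusted fit, Hoxa1 (0.50, edgeR adjusted p = 0.0455) and Hoxa2 (0.69, edgeR adjusted p = 0.0303) passed upwards. Hoxa5 passed downwards there (-0.85, edgeR adjusted p = 0.00764). None of these 3 passed over all genes, and with GC and length correction Hoxa2 lost its list-alone call (0.66, SE 0.26). Hoxa9 had 12 counts in the d56 libraries and none in WT, at least 4.78-fold higher if the 12 counts are taken as exact. Hoxa10 had 10 counts and none, at least 3.98-fold higher on the same terms. Both genes passed in the batch-adjusted fit (adjusted p = 0.0202 and 0.0456), at levels under 1 CPM, and with GC and length correction neither passed over all genes. Nnat rose (255 ± 171 against 41.9 ± 36.3 CPM, 2.74, SE 0.22), as did H19 (3.68, SE 0.38), while Grb10 fell (48.7 ± 2.42 against 329 ± 178 CPM, -2.65, SE 0.24) and Plagl1 fell (-2.71, SE 0.63) in the batch-adjusted fit. Higher were the endothelial genes Cdh5 (3.36, SE 0.68) and Tie1 (3.14, SE 0.76) and the globin gene Hbb-bh1 (2.60, SE 0.56), with their reads mainly in replicate 1: Tie1 was at 10.9 against 0.703 CPM there and at 0.487 against 0.349 CPM in replicate 2. In the d56d79 library of Day 0, Cdh5 and Hbb-bh1 were at 0 CPM and Tie1 at 0.402 CPM. Lower were Xist (-5.56, SE 0.66), the retinoic acid target Stra8 (-3.62, SE 0.38), Uty (-2.92, SE 0.44) and Sfmbt2 (-2.29, SE 0.26). With GC and length correction Grb10, Plagl1, H19, Tie1 and Hbb-bh1 lost the call (adjusted p = 0.176, 0.121, 0.12, 0.154 and 0.0572) at log2 fold changes of -2.63, -2.71, 3.70, 3.03 and 2.73, close to those before, and the others named in this paragraph outside HoxA kept it.

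Of the lists at Day 0, fibroblast genes passed upwards (median 0.65, adjusted p = 0.0192) with 3 rises in the batch-adjusted fit, Col3a1 (2.12, SE 0.56), Col1a1 (1.17, SE 0.31) and Col1a2 (1.01, SE 0.28), and 1 fall, Dcn (-1.40, SE 0.40), of 11. Spinal interneuron genes passed upwards (median 1, adjusted p = 0.0192), with Tal1 (1.82, SE 0.43) and Gata2 (1.70, SE 0.45), which also act in blood formation, the 2 rises of 18. None of these 6 genes kept the call after GC and length correction (Col3a1 2.03, Col1a1 0.94, Col1a2 0.87, Dcn -1.44, Tal1 1.76 and Gata2 1.59, adjusted p at least 0.128). The remaining 7 calls were upwards for endoderm (0.0105), epidermis (0.0105), HoxA (0.0445) and HoxD (0.0445), and downwards for progenitors of the ventral cord and motor neurons (0.0105), postmitotic motor neurons (0.0108) and sex-chromosome genes (0.0445). None of the 9 held with an estimated correlation (adjusted p at least 0.839). Of the HoxB list, 1 gene was called at Day 0 with GC and length correction. In the group fit edgeR called 0 genes (66 at an unadjusted p under 0.05, 0 by DESeq2), the batch-adjusted fit 186 (97 higher, 89 lower), the single replicate term 0 with 293 at an unadjusted p under 0.05, and the fit with GC and length correction 46.

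Day 0 and Day 4 share no library, so their calls can be compared. In the batch-adjusted fit 11 genes were higher in d56 on both days where chance gives 0.326 (Fisher's exact test, two-sided, p = 1.94e-14), among them Nnat, H19, Hoxa9, Eif2s3y, Hba-a1, Hba-x and Hbb-bh1. Lower on both days were 10 genes where chance gives 0.275 (Fisher's exact test, p = 1.47e-13), among them Grb10, Plagl1, Uty and Dcn. With 1 gene called in opposite directions, 21 genes had the same direction; with the GC and length correction 6 did, and in the group fit 0 did, where edgeR calls none on either day. Both days compare the same pair of lines, so the shared genes are not independent of the line. Calls of both days also come from 1 fit with 1 spread per gene. Genes such as the globins may vary together, so the chance values and p-values may be too low.

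In the test of whether the d56 effect differed between days, Hoxa7 was the 1 Hoxa gene called over all genes in the batch-adjusted fit (4.10, SE 0.50, adjusted p = 5.38e-11). Hoxa1 also passed there adjusted over the list alone (-0.97, SE 0.30, edgeR adjusted p = 0.00745). Outside HoxA, Hoxb5 of the HoxB cluster was called there over all genes (2.68, SE 0.56, edgeR adjusted p = 0.00191). In the group fit by edgeR Hoxa7 was at 4.19 (SE 1.19, unadjusted p = 0.00907) and did not pass over the list alone (adjusted p = 0.0907). Grb10 fell further at Day 4 than at Day 0 (-2.28, SE 0.33; after GC and length correction -2.19, SE 0.57, adjusted p = 0.742), and Slc16a3, a lactate exporter, differed at Day 4 (2.40) and not at Day 0 (0.05), with an interaction of 2.36 (SE 0.35). Stra8 had an interaction of 3.61 (SE 0.60), at -3.62 on Day 0 and -0.01 on Day 4. The batch-adjusted fit called 65 genes, 32 up and 33 down, and 11 with GC and length correction. The group fit called 0 by edgeR, with 42 at an unadjusted p under 0.05, and DESeq2 called 0.

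In d56d79 at Day 4, expression extended to genes further along the cluster. Hoxa9 was at 57.34 CPM against 0.4 in WT and 2.15 in d56, and Hoxa10 (ENSMUSG00000000938) at 25.06 CPM against no read in WT, at least 178-fold higher, and 0.1 CPM in d56. Hoxa7 was at 35.13 CPM, above WT and below d56, and Hoxa6 at 2.64 CPM against 18.29 in WT and 26.5 in d56. Hoxa11 had no read. Against WT in the batch-adjusted fit, Hoxa9 rose by 6.84 (SE 0.53), Hoxa7 by 3.48 (SE 0.34) and Hoxa10 passed (adjusted p = 1.32e-19), while Hoxa6 fell by 1.97 (adjusted p = 0.00369). Against d56, Hoxa9 rose by 4.48 (SE 0.50) and Hoxa10, with 475 counts against 2, passed upwards (adjusted p = 6.73e-18), while Hoxa6 fell by 2.81 (SE 0.43) and Hoxa7 by 1.17 (SE 0.32, adjusted p = 0.0276). The correction for GC and length ended the call over all genes of Hoxa6 against WT (-2.38, SE 0.70) and d56 (-2.98, SE 0.66). It also ended that of Hoxa7 against d56 (-1.29, SE 0.29). The folds were no smaller than before, and adjusted over the list alone these calls held. Hoxa3 and Hoxa4, at 48.8 and 47.85 CPM, passed downwards in the batch-adjusted fit only adjusted over the list alone. Their values were -0.75 and -0.82 against WT and -0.76 and -0.73 against d56. With the correction these list-alone calls held, at -0.89 and -1.09 against WT and -0.81 for each gene against d56. Hoxa1 (-0.70) and Hoxa5 (-0.64) then also passed downwards against WT over the list alone. In the group fit Hoxa7, Hoxa9 and Hoxa10 passed against WT adjusted over the list alone (adjusted p = 0.0261, 0.0153 and 0.0153), Hoxa10 against d56 (adjusted p = 0.0259), and no Hoxa gene over all genes by edgeR, where DESeq2 passed Hoxa9 and Hoxa10 against WT and none against d56. Of these list-alone calls, that of Hoxa7 against WT was lost without WT replicate 1 or 2 at Day 4 (edgeR adjusted p up to 0.181), and that of Hoxa10 against d56 without d56 replicate 2 (edgeR adjusted p = 0.076).

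Outside HoxA, Plagl1 (-6.83, SE 0.53), Grb10 (-4.61, SE 0.36) and Peg3 (-1.68, SE 0.29) fell and Nnat rose (2.67, SE 0.26) in d56d79 against WT at Day 4 in the batch-adjusted fit; these values stand beside those of d56 and use the same WT libraries. H19 depends on the placement of d56d79 with replicate 2: at 59.9 CPM against 152 and 28.6 CPM in WT replicates 1 and 2, it passed upwards in the batch-adjusted fit (1.45, SE 0.34) and was at -0.59 (SE 1.79) in the group fit. Plagl1, Peg3 and Nnat kept the call with GC and length correction, and Grb10 (-4.37, SE 0.60) and H19 (1.31, SE 0.45) lost it. The floor plate list was lower, with 8 of 8 members called in the batch-adjusted fit, among them Sulf1 (-2.34, SE 0.34), Foxa2 (-3.07, SE 0.52) and Ntn1 (-1.72, SE 0.30), and adjusted p = 1.24e-14 for the list (0.683 with an estimated correlation). After GC and length correction 2 of the 8 were called, Sulf1 and Foxa2, and Ntn1 (-1.44, SE 0.36) was not. In the hypoxia and glycolysis list 8 of 17 rose, among them Ldha (2.36, SE 0.27) and Pdk1 (2.17, SE 0.32), with adjusted p = 0.00687 (0.683 estimated); after the correction 2 were called, Ldha and Pdk1. Ribosomal protein genes passed upwards (adjusted p = 9.58e-10, 0.747 estimated), with a median of 0.87 in the group fit, 0.48 in the batch-adjusted fit (3 called of 24) and 0.24 with GC and length correction (0 called). The difference of d56d79 from WT replicate 2 went with transcript length across genes (Spearman's rho -0.6). Germline genes also passed upwards (0.013, 0.783 estimated, 1 called of 11, Mael, a call lost after the correction at 1.75, SE 0.47). Interneuron genes passed downwards (adjusted p = 3e-05, 0.747 estimated, 1 called of 18, Sim1, at 0.0528 against 6.94 ± 8.04 CPM, a call lost after the correction at -4.69, SE 1.15), as did the imprinted list (0.0392, 0.683 estimated). Against d56, Sim1 (0.0528 against 8.11 ± 4.32 CPM) and Sox7, a factor of endoderm and vessels (0.106 against 16.1 ± 17.5 CPM), fell, and Rbp4 (3.54, SE 0.53) and the cell cycle inhibitor gene Cdkn2a (2.82, SE 0.38) rose in the batch-adjusted fit; after the correction Sim1 lost the call (-5.65, adjusted p = 0.0578) and the other three kept it.

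By count at Day 4, edgeR called 0 genes in the group fit for d56d79 against WT (136 at an unadjusted p under 0.05; DESeq2 called 4, Plagl1, Grb10, Hoxa9 and Hoxa10) and 0 against d56 (127; DESeq2 0). The batch-adjusted fit called 430 (186 higher, 244 lower) and 288 (93 higher, 195 lower), and 59 and 50 with GC and length correction. With replicate numbers taken as labelled, a single replicate term gave 697 and 1750, since it sets the d56d79 libraries beside replicate 1. d56d79 has 1 library per day, and its place with replicate 2 was read from the data, so these values compare it in effect with 1 library per line.

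At Day 0 Hoxa10 had 15 counts in d56d79 (3.01 CPM) and none in WT, at least 20.1-fold higher (adjusted p = 0.000466 in the batch-adjusted fit), and no other Hoxa gene was called over all genes. In that fit Nnat (83.4 against 41.9 ± 36.3 CPM, 2.19, SE 0.29) and H19 (3.54, SE 0.55) rose and Grb10 (59.1 against 329 ± 178 CPM, -2.12, SE 0.33) fell against WT, while Plagl1 did not differ detectably (-0.26, SE 0.96, adjusted p = 1). The sizes for Nnat and H19 depend on the placement of d56d79 with replicate 2, where WT had Nnat at 16.2 CPM against 67.5 CPM in replicate 1; the group fit gave 0.99 (SE 0.99) and 1.90 (SE 1.74). Against d56, Stra8 (66.3 against 2.18 ± 2.59 CPM, 4.05, SE 0.42), Cdkn2a (2.44, SE 0.35) and Dmrt1 (1.94, SE 0.31), a gonadal factor, rose, and the opioid precursor gene Penk (-3.70, SE 0.65) fell. The batch-adjusted fit called 38 genes against WT (18 higher, 20 lower) and 80 against d56 (32 higher, 48 lower). With GC and length correction it called 3 (Nnat, Gm13714 and Gm10059, the last named after its values were seen) and 4 (Stra8, Gm364, Cdkn2a and Dmrt1). In the group fit edgeR called 0 against each, with 84 and 126 at an unadjusted p under 0.05, DESeq2 called 0 and 0, and a single replicate term as labelled gave 1633 and 2312.

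From ESC to Day 0 in WT, neural progenitor genes rose and naive pluripotency genes fell in the batch-adjusted fit. Here that fit sets ESC in effect against replicate 1 of Day 0. The WT replicates 1 and 2 of Day 0 differed widely, with Hoxa1 at 156.43 and 13.39 CPM and Hoxa2 at 33.5 and 1.63 CPM. By the same fit Hoxa1 rose by 5.77 (SE 0.39), Hoxa2 by 6.20 (SE 0.54) and Hoxa3 by 4.77 (SE 0.44). Hoxa9, Hoxa10 and Hoxa11 had 5, 10 and 15 counts in ESC and none in WT at Day 0. In the batch-adjusted fit 8 of 12 neural progenitor genes rose and 1 fell, among the rises Sox3 (3.91, SE 0.33), Msi1 (3.68, SE 0.33) and Irx3 (3.34, SE 0.33), and 19 of 20 naive pluripotency genes fell, among them Esrrb (-5.61, SE 0.31) and Klf4 (-4.68, SE 0.35). Of 16 genes of the retinoic acid response 11 rose, among them Crabp1 (2.70, SE 0.31) and Stra6 (4.56, SE 0.57). Fibroblast and feeder genes fell, 9 of 11, among them Col3a1 (-6.80, SE 0.47) and Fbln2 (-7.00, SE 0.37). By camera in the group fit the naive pluripotency (adjusted p = 1.14e-13) and fibroblast (2.36e-08) lists passed downwards and the neural progenitor (0.191) and retinoic acid (0.0832) lists did not pass; with an estimated correlation none of the 4 passed (adjusted p = 0.11, 0.408, 0.931 and 0.918). The group fit called 0 genes by edgeR, with 977 at an unadjusted p under 0.05, and DESeq2 called 116. The batch-adjusted fit called 4754 (2340 higher, 2414 lower), with ESC placed with replicate 1 as labelled. ESC WT is 1 library.

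ESC of d56 and WT, 1 library each, gave ratios with counting intervals (95%, exact) and no test. The median ratio of the 10 Hoxa genes above the floor was 1.97, with all 10 above 1 under each of the 3 scalings, at 0.780 to 4.12 CPM in d56. A scaling moves all ratios by 1 factor, so this agreement adds little. Fibroblast and feeder genes were also higher in d56, so the cells that a gene's reads came from cannot be told. Only the intervals of Hoxa3 (3.2, 1.56 to 7.08) and Hoxa5 (3.99, 1.93 to 9.05) exclude 1. Hoxa7 had a ratio of 1.67 (0.984 to 2.87). The neighbouring noncoding gene Halr1 went the other way, with 62 counts (5.89 CPM) in WT and 0 in d56. Of the 14 tested neighbours and noncoding genes of the cluster, 7 were higher in d56 (median log2 ratio 0.04). At Day 0 Halr1 was at 0.24 and 7.91 CPM in d56 and at 1.06 and 24.33 CPM in WT (replicates 1 and 2). The largest ratios were those of Nnat (184 against 7.22 CPM, 25.6, interval 20.3 to 32.6), Slc35d3 (19) and Foxq1 (17.9), and among the smallest were Dusp27 (0.0199) and Sept1 (0.021). Grb10 was at 108 against 95.9 CPM, a ratio of 1.13. The HoxA list's median log2 ratio (0.65) lay at percentile 95.8 of random lists of like expression, beside lists of cell types further out: endoderm (1.41, percentile 100), fibroblast and feeder (1.05, percentile 100), neural progenitor (0.95, percentile 100) and naive pluripotency (-0.61, percentile 0). The difference went with transcript length across genes (Spearman's rho 0.48), and ribosomal protein genes were at -0.48 (percentile 0.04). Those were at -0.13 (percentile 18.4) with GC and length correction, the HoxA list at 0.77 (percentile 96.8), endoderm at 0.88, fibroblast and feeder at 0.70, neural progenitor at 1.15 (percentile 100 each) and naive pluripotency at -0.47 (percentile 0). Intervals cover counting error only.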

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

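All tests of explanations in this part were chosen after the results were seen; the interaction test itself was planned, and its batch-adjusted form was added after seeing the data. A difference of the d56 effect between Day 4 and Day 0, by the interaction test, picked out the results below. Genes were taken only from the Hoxa genes and those that the naming rule had picked in other comparisons. A gene picked for a call on 1 day is more likely to differ between days. They are a part of the 65 genes called in the batch-adjusted fit. Gpc3 (-2), Robo3 (4.4) and Hoxb5 (2.68), among others, were called there and lie outside that part.

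Among the genes so taken, the interaction in the batch-adjusted fit (Day 4 minus Day 0, log2) was positive for Hoxa7 (4.1), Stra8 (3.61), Gm11019 (2.8), Slc16a3 (2.36), E530001K10Rik (2.3) and Sfmbt2 (1.78). It was negative for Heph (-3.72), Cpm (-3.03), 2610018G03Rik (-2.41), Grb10 (-2.28) and Atp2a3 (-2.28). None of these passed in the group fit by edgeR, where the unadjusted p was 0.00907 for Hoxa7, 0.0143 for Cpm and 0.0166 for Heph, and 0.0516 or more for the others; edgeR found 42 genes at an unadjusted p under 0.05 there, and DESeq2 called 0 genes.

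Among lists in the group fit, the median interaction was positive for germline (1.65), hypoxia and glycolysis (0.77), postmitotic motor neuron (0.49) and ventral and motor neuron progenitor (0.47) genes. It was negative for endoderm (-1.9), floor plate (-1.79), spinal interneuron (-1.41), epidermis (-1.16), fibroblast and feeder (-0.95) and naive pluripotency (-0.29) genes. These passed by camera with a preset correlation, and none passed with an estimated one (adjusted p at least 0.337).

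Hoxa7 was higher in d56 at Day 4 and not detectably so at Day 0. A GC or length trend is argued against: after its removal the fold change was 4.55 (SE 0.26). Reads of the overlapping antisense gene Hoxaas3 are argued against, as Hoxaas3 itself was at -0.42 (SE 0.26). A difference between the lines other than the deletion cannot be told apart from the deletion, since each genotype is taken as 1 line. In d56d79, whose independence of d56 is not given, Hoxa7 was at 3.48 (SE 0.34).

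Grb10 and Plagl1 were lower and H19 and Nnat higher in d56 at Day 4. In ESC, with 1 library each, the ratio of d56 to WT was 25.6 for Nnat, 1.52 for H19, 0.704 (interval 0.406 to 1.2) for Plagl1 and 1.13 (interval 1.03 to 1.23) for Grb10, which was not lower there. A GC or length trend is argued against, with 4 of 4 genes still beyond 2 SE at Day 4 after its removal. Of them 2 kept an adjusted p under 0.05; Grb10 went from -4.93 (SE 0.27) to -4.82 (SE 0.45, edgeR adjusted p = 0.0683) and H19 from 3.53 (SE 0.30) to 3.41 (SE 0.38, edgeR adjusted p = 0.0808). Their calls ended at folds little changed, with larger SE and with fewer total degrees of freedom (from 74.9 to 4.64 and from 25.1 to 5.19).

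That the whole of it follows the Hoxa7 rise is argued against for Grb10, H19 and Nnat, since 3 of 3 were called at Day 0, where Hoxa7 was at 0.54, and stayed beyond 2 SE with GC and length correction (-2.63, SE 0.41; 3.70, SE 0.53; 2.70, SE 0.17), though only Nnat kept its call. The further fall of Grb10 from -2.65 at Day 0 to -4.93 at Day 4 went with the rise (interaction -2.28, SE 0.33; after the correction -2.19, SE 0.57, edgeR adjusted p = 0.742), so whether that part follows Hoxa7 stays open. For Plagl1 it stays open too: its -2.71 (SE 0.63) at Day 0 rests on levels near the floor, at most 3.52 CPM, and mainly on replicate 1 (0.236 against 3.52 CPM, and 0.365 against 0.698 in replicate 2), and in d56d79 at Day 0 it was at -0.26 (SE 0.96). A difference between the lines other than the deletion, such as a drift of imprinted loci in culture, cannot be told apart from the deletion with 1 line per genotype. At Day 4 in d56d79 4 of 4 were called in the same direction in the batch-adjusted fit, H19 only with d56d79 placed with replicate 2 (1.45, against -0.59 in the group fit).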

How the results depend on the processing

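Of 1339 alternative values of 102 gene results, 1094 kept direction and side of the threshold, 87 lost and 126 gained the call and 32 changed sign. The 28 results past the threshold had 357 of these values, of which 270 kept the call, 87 lost it and none changed sign. Unless stated, the cause was not tested.

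Genes called for d56 against WT (0 at Day 4, 0 at Day 0) became 119 and 186 with the day-wise replicate block, 41 and 46 with GC and length correction too, and 3 at Day 4 by DESeq2. The interaction (0) became 65 day-wise and 11 with GC correction. WT Day 4 against Day 0 (811) became 11557 day-wise, 7531 with the replicate block, also with d56d79 placed with replicate 2, 3079 by DESeq2, 1836 with no filter and 0 to 0 without 1 replicate, which leaves fewer libraries. For d56d79 against WT and d56 at Day 4 (0 and 0) the counts were 430 and 288 day-wise, 59 and 50 with GC correction and 697 and 1750 with the replicate block, and 4 against WT by DESeq2. At Day 0 (0 and 0) they were 38 and 80, 3 and 4, and 1633 and 2312. Day 0 against ESC (0) became 4754 day-wise, 338 with the replicate block, also with d56d79 placed with replicate 2, 116 by DESeq2 and 21 with no filter.

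Hoxa genes called were 2 (d56 Day 4), 2 (d56 Day 0), 8 (WT days), 4 and 4 (d56d79 against WT and d56 at Day 4) day-wise, 1, 3 and 2 for the Day 4 mutant comparisons with GC correction, 3 and 3 for d56d79 with the replicate block, and 1 and 2 by DESeq2 for d56 and d56d79 against WT at Day 4. For WT days (3) they were 0 to 0 without 1 replicate. Genes shared by both days were 21 day-wise and 6 with GC correction. Lists called (5 for d56 Day 4, 9 for d56 Day 0, 6 for d56d79, 24 for WT days) were 0 in each with an estimated correlation, 9, 5 and 12 with the replicate block, 9 and 5 with d56d79 placed with replicate 2, 3 for Day 0 with GC correction, and 3 to 10, 8 to 17 and 3 to 10 without 1 replicate.

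Signs changed in values not called in the group fit. For d56 at Day 4, Hoxa3 became 0.01 with DESeq2 size factors, by DESeq2 and day-wise, and 0.03 with either replicate block. Without 1 replicate the range was -0.45 to 0.51 for Hoxa3, -0.45 to 0.35 for Hoxa4, -0.6 to 0.1 for Hoxa5 and -0.15 to 1.96 for Hoxa6. At Day 0 it was -1.75 to 3 for Hoxa1, -1.59 to 3.86 for Hoxa2, -2.74 to 1.82 for Hoxa3, -1.13 to 1.52 for Hoxa4, -0.31 to 2.24 for Hoxa7, -0.51 to 9.18 for Hbb-bh1, -0.1 to 3.48 for Gbp1 and -5.46 to 1.45 for Gm12578. For WT days Hoxa1 had -0.7 to 2.92. With d56d79 placed with replicate 2, Hoxa1 and Hoxa2 became 0.08 and 0.32 against WT and 0.45 and 0.56 against d56 at Day 4; against d56, without 1 replicate, they had -0.19 to 0.02 and -0.12 to 0.01. The median Hoxa ratio in ESC (1.97) became 2.17 with GC and length correction. Depth leaves Hoxa9, Hoxa10 and Hoxa11 near or under the floor (0.171 to 0.534 CPM) in most libraries.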

Other observations

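The ESC libraries of d56 and WT differed in lists of cell type and state. Fibroblast and feeder genes were higher in d56, with a median log2 ratio of 1.05 over 11 genes and 10 of 11 above 0 (percentile 100 of random lists); Col1a1 was at 1730 against 410 CPM and Fn1 at 4090 against 1390 CPM. Endoderm genes (1.41, percentile 100) and neural progenitor genes (0.95, percentile 100) were also higher, among them Cubn at 15.7 against 2.09 CPM. Naive pluripotency genes were lower (-0.61, percentile 0), with Pou5f1 at a ratio of 0.689, Nanog at 0.627 and Esrrb at 0.378, and so was the list of genes of a state resembling the early embryo (-1.37, percentile 0.02). The difference also went with transcript length across genes (Spearman's rho 0.48), and ribosomal protein genes were lower (-0.48, percentile 0.04). With each library's trend on GC content and length removed, a correction chosen after seeing the data, ribosomal protein genes were at -0.13 (percentile 18.4), fibroblast and feeder genes at 0.70, endoderm genes at 0.88 and neural progenitor genes at 1.15 (percentile 100 each), and naive pluripotency genes at -0.47 (percentile 0). The values of single genes above are uncorrected. With 1 library per line there is no test of these ratios.

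Slc16a3, a lactate exporter, was called higher at Day 4 in both mutant lines in the batch-adjusted fit. It was at 42.6 and 5.69 CPM in d56, at 13 CPM in d56d79 and at 8.58 and 0.894 CPM in WT. For d56d79 the size depends on its placement with replicate 2 (3.65, SE 0.36, against 1.46 in the group fit). At Day 0 it was far higher, at 164 and 107 CPM in WT and 228 and 81.5 CPM in d56.

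The tests below were chosen after the split of the libraries was seen. The Day 0 and Day 4 libraries split by replicate number, with both d56d79 libraries on the replicate 2 side. GC content goes with it in each of the 4 groups with 2 libraries (Spearman's rho across genes between -0.67 and -0.77; genes are not independent replicates). Transcript length as its cause is argued against (largest rho -0.2). After removal of the GC and length trend by splines, the groups' replicate differences still correlated at 0.53 to 0.88 across genes. The trend as removed was thus not the whole of it. A trend that the splines capture only in part would leave such a correlation too, so GC content and length as the whole cause stay open. A difference in library preparation or sequencing between replicates stays open, as the labels name no batch; no biological explanation was tested.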
